A study of Mus musculus with 3 samples.

How the data were processed

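Polysomal RNA from bone marrow cells of WT mice (2 libraries) and Mat KO mice (1 library) was analysed from the deposited gene tables, and groups were taken from the genotype and title labels. The Mat KO library carries no replicate number in the labels and is named 1 here. Per the labels' protocols, cells were incubated with cycloheximide, lysed, and polysomal RNA was separated on a linear sucrose gradient. Per the submitters' processing notes, Trimmomatic, HISAT2 2.1.0 and HTSeq 0.11.2 were used with the build GRCm38. The annotation release, the strand setting and the rRNA depletion or poly(A) selection are not given in the sources used here. The deposited values are raw counts of reads per Ensembl gene, not normalized by the authors, for 48795 gene identifiers and 5 summary lines of HTSeq. Total RNA matched to the polysomal RNA was not analysed here, so no translational efficiency was computed.

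The summary lines name no gene and were left out of library sizes and tests. Of all reads recorded, 427500 in WT 1, 2035709 in WT 2 and 1259524 in the Mat KO library, 15.1%, 11.8% and 9.99% were assigned to genes. Reads falling on several overlapping genes were 33.5%, 74.3% and 66.1%, reads outside any gene 43.9%, 9.68% and 19.6%, and reads aligned to several places 7.44%, 4.27% and 4.27%. A count of 0 allowed 46.5, 12.5 and 23.8 CPM, and 1.44, 13.04 and 2.08 per 10000 counts outside Lars2, CT010467.1, mt-Rnr1 and mt-Rnr2, taking 3 counts as the limit of a count of 0. Reads carry no molecular identifiers, so intervals and limits cover counting error only. Fold bounds against a count of 0 take WT 1 at its observed share and leave out its own counting error. They also take each read as an independent molecule, so they are too high where reads are duplicates. Gene names, biotypes and coordinates came from GENCODE release M21 (GRCm38), which held 48349 of the identifiers and lacked 446.

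Genes were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test, with TMM factors, filterByExpr by group (minimum count 10, minimum total 15), a prior count of 2 and Benjamini-Hochberg adjustment at a false discovery rate of 0.05. With 2 libraries against 1 there is 1 residual degree of freedom, and the lone Mat KO library is assumed to vary like WT. Standard errors were computed as the absolute log2 fold change divided by the square root of the F statistic. The size rule needs a log2 fold change of at least 1 and a distance from the Mat KO library to the nearer WT library larger than the distance between the WT libraries on log2 CPM. It was also run with each WT library as the lone library. DESeq2 1.42.0 and limma 3.58.1 were run beside edgeR. In simulated counts with a low dispersion of 0.01 on 581 genes, the test recovered 72.2% of genes changed 4-fold and 87.6% of genes changed 16-fold with 2 of 387 unchanged genes called. At the estimated dispersion of 3.88 on 600 genes, it recovered 0 of 59 and 0 of 62.

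Before the data were examined, 39 gene lists were fixed, with 1327 symbols, of which 1317 matched. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists tested, and again with an estimated correlation. A minimum of 3 tested members was chosen after the data were seen, and 13 lists met it. Summed counts per list are given with 95% Wilson intervals from SciPy 1.17.1, relative to counts outside the 4 most counted features and, where this changed the reading, to counts of nuclear protein-coding genes other than Lars2, both scales chosen after the data were seen. In the median at the bound, a member at 0 in a group was set to 3 counts over that group. The rule for named genes, fixed before the data were examined, took the detected genes of the Dlk1-Dio3 locus, up to 12 genes in each direction past the false discovery rate, the members of each list described that passed it or otherwise the 2 with the highest mean expression, the sex-linked genes and the 5 genes with the most counts. No gene passed the false discovery rate. The values of a list member that this rule names are not reported here. Genes named outside this rule, Malat1, Anp32b and the genes of the tissue lists among them, were chosen after their values were seen. After the data were seen, 8 tissue lists were added, of pancreatic acinar, liver, skeletal muscle, lung, brain and kidney genes, marrow blood cell markers, and mitochondrial aminoacyl-tRNA synthetases other than Lars2. To test thin sampling, also after the data were seen, the counts of WT 1 over nuclear protein-coding and immunoglobulin genes, without Lars2, were thinned 1000 times to the number of such genes detected in another library, 573 in the Mat KO library and 378 in WT 2.

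Alternatives were other size factors, upper quartile scaling, library sizes without globin, immunoglobulin and mitochondrial genes, no filter, a filter at a mean of 50 counts, protein-coding genes alone, a loess trend on GC content and exon length removed with a span of 0.75, other tools, a prior count of 0.5, each WT library left out, and an estimated camera correlation. Library sizes without the 4 most counted features, total counts alone, and other scalings of the test with WT 2 as the lone library were added after the data were seen. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures.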

Results

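Polysomal RNA of mouse bone marrow cells was sequenced from wild-type (WT) mice, with 2 libraries, and from mice of the genotype Mat KO, with 1 library. Per the labels' protocols, cells were treated with cycloheximide, which holds ribosomes on their mRNAs, and polysomes were separated on a sucrose gradient. Which gradient fractions were sequenced, and whether the tables hold all reads, is not given in the sources used here. The series title places the work on small nucleolar RNAs (snoRNAs) of the imprinted Dlk1-Gtl2 locus, rRNA modification and translation, and the comparison asks which RNAs differ in the polysomes of Mat KO marrow. The 3 libraries held 64547 gene-assigned counts in WT 1, 239429 in WT 2 and 125871 in the Mat KO library. Genes with at least 1 count numbered 4349 in WT 1, 425 in WT 2 and 642 in the Mat KO library, and 51 genes had a count in all 3 libraries. There is no replicate of the Mat KO library, so no spread can be given for it. The p-values for Mat KO against WT rest only on the spread between the 2 WT libraries. The labels do not say whether these came from separate mice, so that spread may be technical.

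Of the locus named in the series title, 3 listed genes had a count, and only in WT 1. Meg3 (Gtl2, ENSMUSG00000021268, GRCm38 chromosome 12 from 109541001 to 109571726), a maternally expressed long noncoding RNA, had 28 counts in WT 1, 0 in WT 2 and 0 in the Mat KO library. Rian, another maternally expressed noncoding RNA of the locus and a host of box C/D snoRNAs, had 1, 0 and 0 counts. Ppp2r5c, a phosphatase subunit gene flanking the locus, had 4, 0 and 0 counts. The other genes among the 22 matched for the locus, Dlk1, Rtl1 and Dio3 among them, had 0 counts in every library. Over the maternally expressed list, WT 1 held 13.9 counts per 10000 counts outside the 4 most counted features (95% Wilson interval 9.66 to 19.9), whereas 0 counts allowed up to 2.08 per 10000 in the Mat KO library and up to 13.04 in WT 2. Taken at its observed value, the share in WT 1 was at least 6.67-fold above that of the Mat KO library and 1.06-fold above that of WT 2. The interval of WT 1 reaches below the 13.04 allowed in WT 2, so no difference from WT 2 is shown. The 0 of WT 2 is limited by depth, so the difference from the Mat KO library rests on WT 1 alone. Of the 4349 genes with a count in WT 1, 293 had one in the Mat KO library. Globin, granule and liver genes, with 401, 613 and 826 counts in WT 1, were at 0 there too. A loss of Meg3 by genotype therefore cannot be told apart from the content of this library. In edgeR's quasi-likelihood test Meg3 had a log2 fold change of -3.50 with a standard error of 4.48 and an adjusted p of 0.729. The 1507 annotated snoRNA genes and the 2202 miRNA genes had 0 counts in all libraries.

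Lars2 and annotated ribosomal RNA features filled most of the gene-assigned counts of each library, which were 15.1%, 11.8% and 9.99% of the reads recorded. Lars2, the gene of mitochondrial leucyl-tRNA synthetase (chromosome 9 from 123366927 to 123462666), took 42.8% of the gene-assigned counts in WT 1, 49.8% in WT 2 and 61.5% in the Mat KO library. CT010467.1, annotated as rRNA (chromosome 17 from 39846353 to 39848827), took 18.5%, 17.3% and 16.3%. Its exons overlap those of Gm42418 over 73.9% of their length on the opposite strand and those of AY036118 over 37.4% on the same strand. The strand setting of the counting is not given in the sources used here. Reads falling on several overlapping genes were recorded apart, so the counts of CT010467.1 may leave out reads from these shared stretches. How many is not known. The mitochondrial rRNAs mt-Rnr1 and mt-Rnr2 together took 6.22%, 31.9% and 10.8%. These 4 features made up 67.6% (Wilson interval 67.3 to 68.0) of the counts in WT 1, 99.0% (99.0 to 99.1) in WT 2 and 88.5% (88.4 to 88.7) in the Mat KO library. Nuclear protein-coding genes other than Lars2 kept 28.8%, 0.510% and 6.37%, which is 18576, 1220 and 8021 counts. The fifth most counted feature, A130071D04Rik (chromosome 1 from 138161820 to 138167683), lies within an intron of Ptprc on the same strand and had 106, 752 and 3560 counts.

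**Figure D1:**
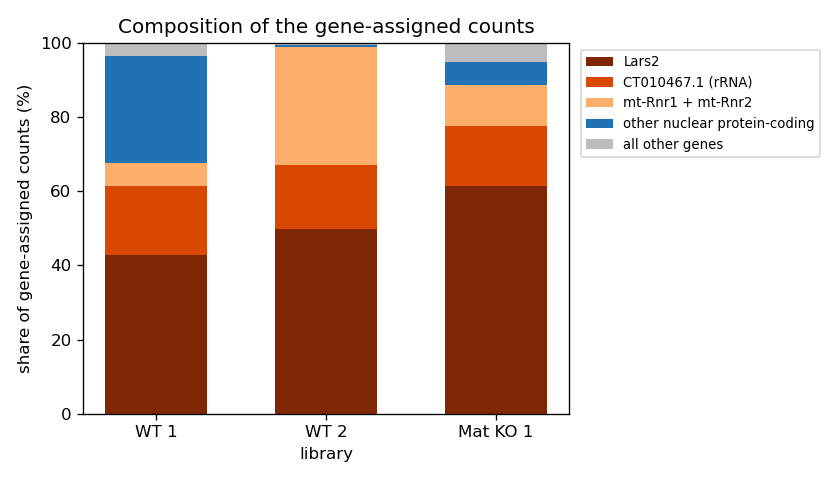
Stacked bars give the share (%) of gene-assigned counts taken by Lars2, CT010467.1, the mitochondrial rRNAs, other nuclear protein-coding genes and all other genes in each of the 3 libraries. Nuclear protein-coding genes other than Lars2 hold 28.8% of WT 1, 0.510% of WT 2 and 6.37% of the Mat KO library.

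No gene differed between Mat KO and WT in the test across genes. Of 437 genes tested, 0 passed a false discovery rate of 0.05 in edgeR's quasi-likelihood test, 0 had an unadjusted p under 0.05, and the smallest adjusted p was 0.729. DESeq2 and limma-voom also called 0 genes, with 7 and 20 at an unadjusted p under 0.05, and edgeR's likelihood ratio test called 0 with 71. Among the 5 most counted genes, Lars2 had a log2 fold change of -2.03 (standard error 6.25), CT010467.1 -2.46 (5.83), mt-Rnr1 -3.07 (5.68), mt-Rnr2 -4.15 (6.49) and A130071D04Rik 0.91 (4.26). These values depended on the scaling. Total counts alone gave 0.41 for Lars2, -0.14 for CT010467.1, -0.31 for mt-Rnr1, -1.15 for mt-Rnr2 and 3.56 for A130071D04Rik, and leaving the 4 most counted features out of the library sizes gave -3.48, -3.89, -4.59, -5.70 and -0.58. A filter at a mean of at least 50 counts gave -0.08, -0.62, -0.82, -1.68 and 3.06. The tested genes rarely had counts in every library: 346 were at 0 in WT 2, 162 at 0 in the Mat KO library, 85 at 0 in both WT libraries, and 34 were above 0 in all 3. The common dispersion was 3.88, and in simulated data with this dispersion, run on 600 genes, edgeR recovered 0 of 62 genes changed 16-fold, with the 4 most counted features not among the changed genes. The same test with WT 2 set against the other libraries called 4 genes, Lars2, CT010467.1, mt-Rnr1 and mt-Rnr2, with log2 fold changes of 2.83, 2.83, 4.01 and 5.36, and with WT 1 set against the others it called 0. The WT 2 arm is 1 library, and its calls depended on the scaling. With DESeq2-type size factors the log2 fold changes of Lars2, CT010467.1, mt-Rnr1 and mt-Rnr2 stayed large, at 3.36, 3.53, 4.52 and 5.76. With total counts alone mt-Rnr1 and mt-Rnr2 lay at 1.10 and 2.41. With the 4 most counted features left out of the library sizes edgeR also called 4 genes, but with DESeq2-type size factors and with total counts alone it called 0, with 1 gene at an unadjusted p under 0.05 in each, and with total counts alone the log2 fold changes of Lars2 and CT010467.1 were -0.07 and -0.01.

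By size alone, 164 genes differed at least 2-fold with the Mat KO library outside both WT libraries by more than the gap between them, 146 higher and 18 lower. Leaving the 4 most counted features out of the library sizes gave 129 higher and 36 lower. The same rule gave 179 genes when WT 1 was set against the other libraries and 92 when WT 2 was, so the number for Mat KO lay within the range set by the WT libraries. With WT 1 left out, 289 genes were at least 2-fold apart, 235 higher and 54 lower in the Mat KO library, and with WT 2 left out 375 were, 166 higher and 209 lower, which turns the balance. WT 2 was at 0 in 346 of the 437 tested genes, which leaves the rule little room to count a gene as lower. The 85 tested genes at 0 in both WT libraries passed the filter through the Mat KO library alone, so their positive values were fixed in advance. With WT 1 as the lone library the rule gave 171 higher and 8 lower, and with WT 2 14 higher and 78 lower. The excess of higher genes is therefore no support for a Mat KO difference. Among genes singled out after their values were seen, the nuclear noncoding RNA Malat1 had 146 counts in WT 1, 0 in WT 2 and 1270 in the Mat KO library, and Anp32b had 21, 0 and 656. Their adjusted p in edgeR's quasi-likelihood test was 0.780 and 0.729.

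Globin, neutrophil secondary and tertiary granule, plasma cell, and eosinophil, basophil and mast cell transcripts were counted in WT 1 and had 0 counts in both other libraries, while the other marrow cell lists had counts in at least 1 of these. The globin genes had 401 counts in WT 1, 0 in WT 2 and 0 in the Mat KO library, led by Hbb-bs with 168, 0 and 0 and Hba-a1 with 139, 0 and 0. The neutrophil secondary and tertiary granule genes had 613, 0 and 0 counts, led by the calprotectin genes S100a8 with 137, 0 and 0 and S100a9 with 133, 0 and 0. Relative to counts outside the 4 most counted features, the observed share of granule genes in WT 1 was at least 141-fold above that of the Mat KO library. Against WT 2 it was at least 22.5-fold above. For globins the bounds were 92.3-fold and 14.7-fold. Relative to nuclear protein-coding genes other than Lars2, a scale also chosen after the data were seen, the bounds were 88.2-fold and 13.4-fold for granule genes and 57.7-fold and 8.78-fold for globins. All these bounds take each read as an independent molecule. In the Mat KO library 321 of 642 genes had at least 10 counts and 141 had 1, against 413 and 1946 of 4349 in WT 1. If reads there are duplicates, the bounds are too high, by an amount that was not tested. Globin genes are near-identical copies, so the division of counts among them is uncertain. Plasma cell genes had 105, 0 and 0 counts, with Ighg2b at 32, 0 and 0 and Ighg1 at 27, 0 and 0. Eosinophil, basophil and mast cell genes had 12, 0 and 0 counts, a share of 5.74 per 10000 in WT 1, under the 13.04 that a count of 0 allowed in WT 2. Neutrophil primary granule genes had 148, 4 and 28 counts, where the counts of WT 2 and the Mat KO library came from the chaperone gene Calr at 22, 4 and 28. B cell genes had 110, 18 and 1 counts, with Igkc at 79, 0 and 1 and Bach2 at 0, 18 and 0, which is 52.6 (Wilson interval 43.7 to 63.4), 78.2 (49.5 to 123) and 0.693 (0.122 to 3.92) per 10000 other counts. Mature neutrophil genes had 38, 22 and 2, led by Clec4e with 4, 22 and 0 and Mxd1 with 12, 0 and 0, or 18.2 (13.2 to 24.9), 95.6 (63.2 to 144) and 1.39 (0.380 to 5.05) per 10000. In WT 2 all counts of the B cell list came from Bach2 and all of the mature neutrophil list from Clec4e. Erythroid genes had 99, 0 and 22 counts, with Bpgm at 3, 0 and 14 and Epb41 at 10, 0 and 8, and stem and progenitor cell genes had 45, 0 and 22, with Hoxb4 at 0, 0 and 12. The stem and progenitor list lay at 21.5 (16.1 to 28.8) per 10000 in WT 1 and 15.2 (10.1 to 23.1) in the Mat KO library, and the erythroid list at 47.4 (38.9 to 57.6) and 15.2 (10.1 to 23.1). Per 10000 nuclear protein-coding counts they lay at 24.2 (18.1 to 32.4) and 27.4 (18.1 to 41.5), and at 53.3 (43.8 to 64.8) and 27.4 (18.1 to 41.5). The Mat KO library held 990 counts of pancreatic acinar enzyme genes, against 1 in WT 1 and 18 in WT 2. Per 10000 other counts this was 686 (646 to 728.5) in the Mat KO library, 0.478 (0.084 to 2.71) in WT 1 and 78.2 (49.5 to 123) in WT 2. WT 2 thus also lay above WT 1. WT 1, the library with the marrow transcripts, also held 826 counts of liver secreted protein genes, or 395 (370 to 422) per 10000, and 331 of skeletal muscle contractile genes, or 158 (142 to 176), against 26 and 0 counts in WT 2 and 0 and 12 in the Mat KO library. The 26 liver counts of WT 2 were 113 (77.2 to 165) per 10000.

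Of these cell type lists, 4 had at least 3 tested members. The secondary and tertiary granule genes had a median log2 fold change of -3.89 over 10 tested members and passed camera at a preset correlation (adjusted p = 0.00715), but not with an estimated correlation (adjusted p = 0.712). With 1 residual degree of freedom the estimated correlation was 1 for this list, so that setting cannot decide. With no filter on low counts the median was -2.71, and no list passed camera. With members at 0 set at their bound of 3 counts, the median was -4.45. All 10 members were at 0 in WT 2 as well as in the Mat KO library, so the fitted medians are set by the counts of WT 1. They passed the filter, which needs enough counts in 1 library, through WT 1 alone. A negative median was therefore fixed in advance, and camera's result is no support for a Mat KO difference. Globins had a median of -5.05 over 4 members, -5.66 at the bound (camera adjusted p = 0.0736), plasma cell genes -3.46 over 3, -3.98 at the bound (0.152), and primary granule genes -2.71 over 3, -3.13 at the bound (0.238), or -1.61 with no filter. With WT 1 left out, the medians of all 4 lists were 0, but they carry no measurement, since all tested globin, granule and plasma cell genes and 2 of the 3 primary granule genes had 0 counts in both remaining libraries. No member of these lists was called over all genes or adjusted over the list alone.

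Stromal, endothelial and bone cell genes had 773 counts in WT 1, 83 in WT 2 and 47 in the Mat KO library. This was 370 per 10000 other counts (Wilson interval 345 to 396) in WT 1, 361 (292 to 445) in WT 2 and 32.6 (24.5 to 43.3) in the Mat KO library. Per 10000 counts of nuclear protein-coding genes other than Lars2 the list lay at 416 (388 to 446), 680 (552 to 836) and 58.6 (44.1 to 77.8), so whether the WT libraries were alike depended on the scale, while the Mat KO library was lowest on both. Apoe, an apolipoprotein gene, had 158, 62 and 18 counts and Col1a1, a collagen gene of bone matrix, 189, 1 and 0. The WT libraries differed in which members they held: Apoe and Ctsk, with 62 and 16, gave most of the counts of WT 2, where the collagen gene Col1a2 had 134, 0 and 0 and Sparc 99, 4 and 0. The list's median was -3.69 over 10 tested members, -4.48 at the bound (camera adjusted p = 0.0182; adjusted p = 0.712 with an estimated correlation). The estimated correlation was 1 for this list as well, so that setting cannot decide. With no filter the median was -1.53 and the list no longer passed camera. In the test, 0 members were called over all genes or adjusted over the list alone. Of the 10 members, 7 were at 0 in the Mat KO library and 7 in WT 2, and 5 in both, so with WT 1 left out the median of 0 is that of genes with 0 counts in both. These 5 passed the filter through WT 1 alone, so their negative values were fixed in advance.

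**Figure D2:**
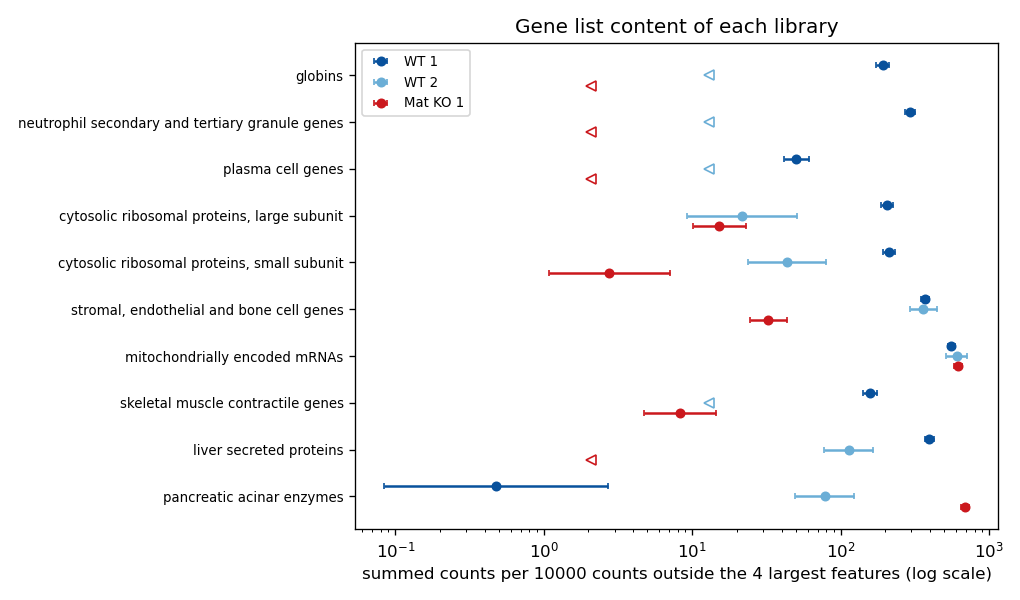
Points give the summed counts of 10 gene lists in each library per 10000 counts outside the 4 most counted features, on a log axis, with 95% Wilson intervals as bars, and open triangles mark the value that a count of 0 allows. Globins, granule genes and plasma cell genes are at 0 in WT 2 and in the Mat KO library. Mitochondrially encoded mRNAs lie at 556, 604 and 621 in WT 1, WT 2 and the Mat KO library, but their nearness depends on this scale. Of all gene-assigned counts they are 1.802%, 0.05805% and 0.7118%.

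Ribosomal protein genes had lower shares in WT 2 and in the Mat KO library than in WT 1, beyond counting error if reads are independent molecules. Translation factors and ribosome biogenesis factors did not follow this order. Large-subunit ribosomal protein genes had 431, 5 and 22 counts in WT 1, WT 2 and the Mat KO library, with Rpl27 at 17, 0 and 14 and Rplp1 at 33, 0 and 0. Small-subunit ribosomal protein genes had 441, 10 and 4 counts, with Rps2 at 23, 4 and 0 and Rps9 at 36, 0 and 1. Per 10000 other counts the small-subunit genes lay at 211 (192 to 231) in WT 1, 43.5 (23.6 to 79.8) in WT 2 and 2.77 (1.08 to 7.13) in the Mat KO library, and the large-subunit genes at 206 (188 to 226), 21.7 (9.29 to 50.8) and 15.2 (10.1 to 23.1). Ribosomal protein genes have many processed pseudogenes, and reads shared with these were outside the counts. The median log2 fold change was -3.07 over 15 small-subunit members, -3.61 at the bound (camera adjusted p = 0.00351), and -2.87 over 11 large-subunit members, -3.47 at the bound (0.0182). With an estimated correlation neither passed, but the estimate was 1 for both lists, so that setting cannot decide. With no filter neither passed camera, with medians of -2.18 for small-subunit and -1.62 for large-subunit genes. Of the tested members, 12 small-subunit and 8 large-subunit genes were at 0 in the Mat KO library and 12 and 9 in WT 2, and 10 and 6 were at 0 in both, so with WT 1 left out the medians of 0 are those of genes with 0 counts in both. Those 10 and 6 genes passed the filter through WT 1 alone, so their negative values were fixed in advance. Translation initiation and elongation factors had 329, 66 and 40 counts, with the elongation factor gene Eef2 at 70, 18 and 6 and Tpt1 at 48, 11 and 1, or 157 (141 to 175), 287 (226 to 363) and 27.7 (20.4 to 37.7) per 10000, which is highest in WT 2, as also per nuclear protein-coding counts at 177 (159 to 197), 541 (427 to 682) and 49.9 (36.6 to 67.8). Their median was -3.87 over 5 members, -4.71 at the bound (camera adjusted p = 0.152), -0.98 with no filter, and -1.94 with WT 1 left out. Ribosome biogenesis factors had 16, 0 and 29 counts, with Ubtf, a cofactor of RNA polymerase I, at 4, 0 and 16 and Ncl at 3, 0 and 13, or 7.65 (4.71 to 12.4) per 10000 in WT 1 and 20.1 (14.0 to 28.9) in the Mat KO library. The snoRNP core and rRNA modification genes had 4, 3 and 0 counts, snoRNA host genes 13, 4 and 0, mitochondrial ribosomal proteins 30, 1 and 0, and the PI3K-mTOR pathway 29, 0 and 0. The observed share of mitochondrial ribosomal proteins in WT 1 was at least 6.90-fold above the Mat KO library, or 4.32-fold relative to nuclear protein-coding counts. No member of these lists was called over all genes or adjusted over the list alone.

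Mitochondrially encoded mRNAs had 1163, 139 and 896 counts, or 556 (526 to 588), 604 (514 to 709) and 621 (583 to 662) per 10000 counts outside the 4 most counted features, a scale chosen after the data were seen. The nearness of these 3 values depends on the scale, which includes A130071D04Rik at 50.7, 3268 and 2467 per 10000. As a share of all gene-assigned counts the list lay at 1.80%, 0.0581% and 0.712%, and the member mt-Co1 had 446, 0 and 128 counts. The respiratory chain genes mt-Nd5 and mt-Cytb had 42, 30 and 323 and 237, 42 and 91 counts. The median log2 fold change of the list was -2.12 over 9 tested members, -2.42 at the bound (camera adjusted p = 0.537), and it turned to 1.19 with WT 1 left out. With DESeq2-type size factors it was -0.86. Nuclear-encoded respiratory chain genes had 220, 10 and 18 counts and a median of -2.87 over 3 members, -3.31 at the bound (0.554), with Atp5b at 17, 6 and 0 and Sdhc at 0, 0 and 15. Heat shock and chaperone genes had 124, 6 and 43 counts, with Hspa8 at 22, 1 and 28 and Hspa5 at 10, 2 and 11. Their median of -1.68, -2.03 at the bound (0.238), was -1.001 with DESeq2-type size factors and turned to 0.09 with WT 1 left out. Autophagy and lysosome genes had 151, 4 and 42 counts, and the 42 of the Mat KO library all came from Ulk1, an autophagy kinase gene, at 0, 0 and 42, while Gabarap had 3, 4 and 0. Their median was -2.87 over 5 members, -3.31 at the bound (0.243). Glycolysis genes had 155, 3 and 14 counts, a median of -3.32 over 4 members and -3.77 at the bound (0.209), with Aldoa at 24, 2 and 0 and Pkm at 37, 0 and 0. With WT 1 left out, the median was that of a gene with 0 counts in both remaining libraries for the nuclear-encoded respiratory chain and autophagy lists, and -0.57 for glycolysis. With no filter the medians were -1.20 for mitochondrially encoded mRNAs, -0.69 for nuclear-encoded respiratory chain genes, which is the median of all genes in that fit, -0.66 for chaperone, -1.38 for autophagy and -1.32 for glycolysis genes. No member of the lists in this paragraph was called over all genes or adjusted over the list alone, and no list other than those on granule, stromal and ribosomal protein genes passed camera at the preset correlation.

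The remaining lists had fewer than 3 tested members, and 0 members called over all genes or adjusted over the list alone. Counts in WT 1, WT 2 and the Mat KO library were 94, 7 and 0 for heme synthesis and iron handling, 81, 1 and 10 for megakaryocyte and platelet genes, and 140, 3 and 16 for monocyte, macrophage and dendritic cell genes. T and NK cell genes had 7, 0 and 1. Mitosis genes had 42, 0 and 0, DNA replication genes 17, 7 and 22, and replication-dependent histone genes 35, 0 and 0. Interferon response genes had 36, 0 and 0, immediate early and NF-kB response genes 35, 0 and 2, integrated stress and unfolded protein response genes 93, 10 and 40, and p53 target and apoptosis genes 29, 0 and 0. Proteasome subunits had 92, 3 and 6 counts, and cholesterol synthesis genes 61, 0 and 0. The sex-linked genes Xist, Tsix, Ddx3y, Kdm5d, Uty and Eif2s3y had 0 counts in every library, so they could not check the samples.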

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

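The scalings by total counts alone and without the 4 most counted features were chosen after the data were seen. The count of 0 genes past the false discovery rate was the same in all alternatives that gave a value, and edgeR had at most 71 genes at an unadjusted p under 0.05, in the likelihood ratio test. Upper quartile scaling gave no value because the quantile was 0. Leaving out a WT library leaves 1 library against 1 with no residual degrees of freedom, so no test was run. The size rule, 164 genes as reported, gave 435 with no filter and 2 at a mean of at least 50 counts, where 4856 and 20 genes were tested. With a WT library left out, under the fold rule alone, it gave 289 to 375. In the other alternatives it gave 150 to 198. The 4 lists past camera's threshold at the preset correlation fell to 0 with no filter, to 0 at a mean of at least 50 counts, where 1 list was left, and to 0 with an estimated correlation. The cause for no filter was not tested. With 1 residual degree of freedom the estimated correlation was 1 for each of the 4 lists, so that setting cannot decide. The filter keeps a gene with enough counts in 1 library. Members at 0 in both WT 2 and the Mat KO library therefore entered through WT 1 alone, with a negative value fixed in advance. The scaling and filter alternatives moved the median log2 fold change of all genes from -0.27 to values between -1.23 and 0.75. No list median changed sign in these, but with WT 1 left out 2 of 13 changed sign and 9 of 13 were 0 because the members at the median had 0 counts in both remaining libraries. No paired analysis was possible because the Mat KO library has no replicate number in the labels and the groups share fewer than 2 numbers. Depth limits WT 2 most, where 2301 counts lie outside the 4 most counted features.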

Other observations

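All tests in this part were chosen after the results were seen, as were the tissue lists. The Mat KO library held transcripts of pancreatic digestive enzymes, with 990 counts in 26 of 31 listed acinar genes, against 1 count in 1 gene of WT 1 and 18 counts in 10 genes of WT 2. Ctrb1, a chymotrypsinogen gene, had 238 counts in the Mat KO library, 3 in WT 2 and 0 in WT 1, and Pnlip, the pancreatic lipase gene, 106, 3 and 0. The trypsinogen genes are close paralogs, so the division of counts among them is uncertain. WT 1 held 826 counts of liver secreted proteins, with Alb, the albumin gene, at 176 and Apoa1 at 76, against 26 in WT 2 and 0 in the Mat KO library. Skeletal muscle contractile genes had 331 counts in WT 1, 0 in WT 2 and 12 in the Mat KO library, led by Myh4 with 61, 0 and 0. Counts in WT 1, WT 2 and the Mat KO library were 45, 1 and 15 for brain genes, 8, 0 and 0 for lung genes, 0, 0 and 0 for kidney genes, and 1, 0 and 7 for mitochondrial aminoacyl-tRNA synthetases other than Lars2. A list of 20 marrow blood cell markers, all of which had a count in WT 1, had 1059 counts there, 0 in WT 2 and 1 in the Mat KO library, the last from Igkc. All 20 were also in lists fixed before the data were examined, while 0 of the 31 acinar genes were.

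The low number of blood cell genes in the Mat KO library and in WT 2 was weighed against thin sampling, tissue origin and genotype. Of 326 nuclear genes in the 12 blood cell lists fixed before the data were examined, 123 had a count in WT 1, 8 in the Mat KO library and 6 in WT 2. Thinning WT 1 to as many detected genes left a mean of 32.2 blood cell genes (22 to 50 over 1000 draws) for the Mat KO library and 23.9 (14 to 35) for WT 2. This argues only against thin sampling of the WT 1 composition by itself. Of the 642 genes with a count in the Mat KO library 293 had one in WT 1, and of the 425 in WT 2 237 had. The draws therefore cannot decide on thin sampling of marrow RNA mixed with other RNA. WT 1 itself held 826 liver and 331 muscle counts, whose origin was not tested, and may not stand for marrow alone. RNA from pancreas is a candidate source of part of the Mat KO library, and how it entered is open. Of the 20 listed acinar genes outside its 50 most counted genes, 75% had a count, against 10% in WT 2 and 0% in WT 1. Per 10000 nuclear protein-coding counts the acinar list lay at 1234 (1164 to 1308) in the Mat KO library, 147.5 (93.5 to 232) in WT 2 and 0.538 (0.095 to 3.05) in WT 1. WT 2 thus also lay above WT 1. The genotype as the cause cannot be told apart from a property of this library, as there is 1 Mat KO library and WT 2, of the other genotype, held 6 of the genes.

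By size alone 164 genes differed for Mat KO, and 2 of the 3 splits of the libraries gave as many, with 179 at the highest other split, but 3 splits cannot give a share under 0.05. The ratio of Lars2 to CT010467.1 counts was 2.31 in WT 1, 2.88 in WT 2 and 3.78 in the Mat KO library, a 1.64-fold range. Lars2 per count of other nuclear protein-coding genes was 1.49, 97.8 and 9.64, a 65.7-fold range. The second range largely follows the share of other nuclear protein-coding genes, at 28.8%, 0.510% and 6.37% of gene-assigned counts. The share of Lars2 rose from 42.8% to 49.8% and 61.5%, while that of CT010467.1 fell from 18.5% to 17.3% and 16.3%. The contrast between the ranges therefore cannot decide what the Lars2 counts are, and they are not shown to be synthetase mRNA. Whether Lars2 shares sequence with rRNA was not tested.

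Counts above 1 were mostly even. Of genes with at least 2 counts, 84.5% had an even count in the Mat KO library, 75% in WT 2 and 68.9% in WT 1. Reads that enter as mates of a pair or as duplicates may be the source. In that case the number of independent molecules is lower than the counts, the intervals given are too narrow and the fold bounds too high. No biological explanation was tested.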
